A study of Mus musculus with 12 samples.

How the data were processed

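RNA was measured by sequencing in 12 libraries of mouse embryonic salivary glands, taken at embryonic day 13.5 and kept for 2 days in culture on filter membranes. The labels give 5 groups: 3 libraries of wild-type glands with the solvent DMSO, 3 with SU5402 at 2.5 µM (called FGFRi, a small molecule that inhibits FGF receptor kinases), and 2 each of WT, HET and HOM glands of a cross in which Cre under the keratin 14 promoter deletes the Fgfr2b isoform of the FGF receptor 2 gene in epithelium. HOM glands carry both deleted copies. A MEK inhibitor named in the culture protocol belongs to no library of this set. All 12 libraries carry the same batch label. Per the labels, total RNA was depleted of ribosomal RNA and made into libraries with NEBNext Ultra II kits.

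The deposited values are raw read counts per gene (unit: counts), whole numbers from 0 with no normalization, and the submitters' processing notes name bcl2fastq, STAR and the genome build GRCm39 without versions. The counting program, the use of read strand and the annotation release are not given in the sources used here, so genes that overlap on opposite strands, and paralogs or retrogenes that share reads, were read with caution. Symbols and gene types came from GENCODE M21, an annotation of the earlier build GRCm38, by matching of Ensembl identifiers: 52403 of 52636 identifiers had a symbol. No coordinates are given for that reason.

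Total counts ran from 6043701 to 22322182 per library. Because no molecular identifiers were reported, reads are not independent molecules, and any floor set from a count of 0 covers counting error only. Where every library of a group had a count of 0, no fitted fold change is given as a size: levels are printed, or a fold against a floor of 3 counts over the whole group, from group means of CPM averaged on the log2 scale where 2 control groups were joined. Medians of lists with such genes are given as fitted and also with these genes at that floor. The labels do not say which libraries came from separate embryos or litters, so each p-value measures spread between these libraries, which may be partly technical.

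Differential expression was tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test, with TMM normalization and filterByExpr at its defaults (minimum count 10, minimum total 15), which kept 15859 genes. The model held all 12 libraries with 1 coefficient per group and no covariate (residual df 7, prior df 7.96, biological coefficient of variation 0.110). The contrasts were FGFRi against DMSO, HOM against the mean of the WT and HET groups, HOM against each of those groups, HET against WT, DMSO against WT, and the FGFRi effect minus the HOM effect. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested in 1 contrast, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. Levels are TMM-normalized CPM, edgeR's counts scaled to a common library size, given as mean ± SD.

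Before the data were examined, 39 gene lists with 734 entries were fixed, 3 of them for library quality, together with the tests, the alternatives and the rule for named genes. The 36 biological lists, each with at least 4 tested members, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists. Camera with an estimated correlation, and fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes, were the alternatives. Which lists are described member by member was chosen after their results were seen. Named genes are a panel of 19 FGF, end bud, basal and junction genes in both main comparisons. Added to it are the 8 largest rises and 8 largest falls among called genes with at least 5 CPM, no overlap between the compared libraries and a symbol that is no clone or pseudogene. Each described list gives up to 4 members in order of p, the test of the difference 6 genes per direction by p, the overlap 6 per direction by the smaller of both changes, and HET or DMSO against WT 5 per direction by p. Some genes that this rule names are not reported here.

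Alternatives were other scalings (DESeq2 size factors, library totals, counts of the pan-epithelial list), other filters, removal of mitochondrial, structural RNA and erythroid genes, models of the compared groups alone, a block by replicate number, each library left out in turn, DESeq2 1.42.0, limma-voom, a minimum change of 1 on the log2 scale, and WT or HET alone as controls. After the data were seen, more were added: protein-coding genes alone, removal of 5 ribosomal-RNA-like features, a covariate for the sex of the library, removal of the pair of libraries high in stratified-epithelium genes, and a block with the WT numbers crossed. The model was tested on simulated data drawn from a negative binomial model with the means and dispersions of these libraries. Known changes of 1.5-, 2- and 4-fold were set in 67, 67 and 66 genes, up or down at random, with no other group effect. The model recovered 41.8%, 64.2% and 87.9% of these changes for FGFRi, with 11 false calls, and 50.7%, 70.1% and 68.2% for HOM, with 8. For the difference between both effects it recovered 11.9%, 47.8% and 74.2%, with 7 false calls. Changes in as many genes as the real comparisons called were not simulated, so these false calls do not carry over to them. All 12 libraries were used.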

Results

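Bulk RNA sequencing was read in 12 libraries of cultured mouse embryonic salivary glands: 3 with DMSO, 3 with the FGF receptor inhibitor SU5402 (FGFRi), and 2 each of wild-type (WT), heterozygous (HET) and homozygous (HOM) glands of the epithelial Fgfr2b deletion cross. Total counts were 6043701, 18900097 and 6254723 in DMSO 1 to 3, and 7115379, 7523505 and 16938455 in FGFRi 1 to 3. They were 13900648 and 11001035 in WT, 13840973 and 11679114 in HET, and 12007457 and 22322182 in HOM. Ribosomal-RNA-like features took 16.3% to 40.7% of the counts of a library, and mitochondrial genes 3.93% to 14.2%. By Xist, the RNA that coats the inactive X chromosome, and 4 Y-linked genes, both HOM libraries were female, the 4 WT and HET libraries and DMSO 2 were male, and the other DMSO and all 3 FGFRi libraries were female.

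Fgfr2 (ENSMUSG00000030849) is the gene whose Fgfr2b isoform the cross deletes, and it encodes a receptor of the family that SU5402 inhibits. It was read at 95.0 ± 5.02 CPM in DMSO and 76.7 ± 3.44 CPM in FGFRi (SD, n = 3 each). Its level was 100 ± 1.26 CPM in WT, 93.0 ± 9.64 in HET and 91.8 ± 3.67 in HOM (SD, n = 2 each). With the inhibitor it fell by 0.31 ± 0.08 on the log2 scale (SE, adjusted p = 0.00942), a direction that turned to 0.13 when libraries were scaled to epithelial genes, and a call lost without FGFRi 2 (adjusted p = 0.0635). In HOM it differed from controls by -0.071 ± 0.08 (adjusted p = 0.685). Counts over the whole gene do not separate the exon of the Fgfr2b isoform, so this level checks nothing about the deletion.

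Inhibition of FGF receptors for 2 days was compared with DMSO to ask how FGF signalling shapes cell fate and cell junctions in the gland. Of 23 targets and feedback inhibitors of FGF/ERK signalling 14 fell (adjusted p = 0.0366 with an estimated correlation): Etv4, an ETS transcription factor induced by FGF, was read at 16.6 ± 1.96 CPM in FGFRi and 38.5 ± 3.15 in DMSO (SD, n = 3 each), a log2 change of -1.21 ± 0.11. Of 22 genes of the distal end bud, from which acini form, 13 fell (adjusted p = 0.0919 with an estimated correlation), among them the receptor gene Kit, at 0.481 times its DMSO level, and Bpifa2, a secreted salivary protein, at 0.0825 times. Of 17 mesenchymal, 16 skeletal muscle and 26 Wnt signalling genes, 14, 15 and 15 rose and 0, 0 and 1 fell, and none of these lists was called with an estimated correlation (adjusted p = 0.0850, 0.108 and 0.0919). Of 15859 genes tested, 1543 were higher and 1702 lower with the inhibitor, 709 and 113 of them by at least 2-fold.

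Of 23 tested FGF/ERK response genes, 14 fell, 0 rose and 9 did not pass, with a median log2 change of -0.42 (camera adjusted p = 8.05e-12; adjusted p = 0.0366 with an estimated correlation). Adjusted over the list alone, 15 fell. Etv1 fell by 1.28 ± 0.15 (SE, adjusted p = 4.54e-05), and Etv5, the partner of Etv4, by 0.73 ± 0.10 (adjusted p = 1.68e-04). Epha2, an ephrin receptor, fell by 0.89 ± 0.11 (adjusted p = 8.68e-05), and Shisa2, which restrains FGF and Wnt receptors, by 0.88 ± 0.11 (adjusted p = 1.12e-04). The feedback inhibitors Spry1, Spry2 and Spry4 fell by 0.38, 0.31 and 0.40, and the ERK phosphatase gene Dusp6 by 0.42, directions that turned to 0.068, 0.12, 0.048 and 0.023 under epithelial scaling. Under that scaling, the list median moved to 0.02, with 8 members lower and 3 higher. The Spry2 call was lost without any 1 of DMSO 1, DMSO 2, DMSO 3, FGFRi 1 or FGFRi 2 (adjusted p up to 0.197). That of Spry4 was lost without DMSO 2, FGFRi 1 or FGFRi 2 (up to 0.158), and that of Dusp6 without DMSO 1 or FGFRi 1 (up to 0.0742).

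Among 22 tested markers of distal end buds and acini, 13 fell, 0 rose and 9 did not pass, with a median of -1.08 (camera adjusted p = 1.35e-15; adjusted p = 0.0919 with an estimated correlation). Adjusted over the list alone, 17 fell, and under epithelial scaling 12 were lower and 2 higher. Kit fell by 1.06 ± 0.10 (SE, adjusted p = 7.83e-06), Bpifa2 by 3.60 ± 0.40 (adjusted p = 3.17e-05) and the water channel gene Aqp5 by 1.48 ± 0.19 (adjusted p = 1.11e-04). Sox10, a transcription factor of acinar progenitors, fell by 0.66 ± 0.10 (adjusted p = 4.80e-04), whereas Sox9 differed by -0.21 ± 0.09 (adjusted p = 0.108), which turned to 0.23 under epithelial scaling. Also lower were Cldn10, a claudin, by -1.48 ± 0.20, Lpo, the secreted lactoperoxidase, by -2.06 ± 0.30, and Dcpp2, a secreted salivary protein whose paralogs share sequence, by -1.99 ± 0.42 on the log2 scale. Without DMSO 2, Bpifa2 changed by -2.91, and without FGFRi 3, Lpo and Dcpp2 changed by -2.75 and -2.68.

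Tight-junction genes were lower too. Of 27 tight-junction genes, 17 fell, 0 rose and 10 did not pass (median -0.46, camera adjusted p = 8.78e-12; adjusted p = 0.0366 with an estimated correlation), and 18 fell adjusted over the list alone. The scaffold genes Cgnl1 and Cgn fell by 0.94 ± 0.09 and 0.62 ± 0.08, and Cldn7 by 0.75 ± 0.10 (SE, n = 3 each). Of 15 pan-epithelial genes 12 fell, 0 rose and 3 did not pass (median -0.37, camera adjusted p = 3.72e-08; adjusted p = 0.124 with an estimated correlation), and 14 fell adjusted over the list alone. Llgl2, a polarity gene, and the membrane protease gene St14 fell by 0.61 ± 0.09 and 0.65 ± 0.10, and the adhesion gene Epcam by 0.49 ± 0.08. Cdh1, the E-cadherin gene, fell by 0.37 ± 0.09, a call lost without FGFRi 1 (adjusted p = 0.0752), and the splicing factor gene Esrp1 by 0.37 ± 0.06, directions that turned to 0.073 and 0.077 under epithelial scaling. P-cadherin, Cdh3, differed by -0.23 ± 0.10 (adjusted p = 0.141). Summed over the pan-epithelial list, counts were 1245 ± 72.4 CPM in FGFRi and 1694 ± 108 in DMSO (SD, n = 3 each), and under this scaling 8 tight-junction genes were higher and 5 lower.

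The stress-response list held some of the largest falls: of 18 tested genes of the unfolded protein and integrated stress responses, 12 fell, 2 rose and 4 did not pass (median -0.43, camera adjusted p = 9.05e-09; adjusted p = 0.0919 with an estimated correlation), with the same counts adjusted over the list alone. Trib3, a pseudokinase gene induced by amino acid stress, fell by 2.60 ± 0.21 (SE, adjusted p = 2.95e-06). Chac1, which degrades glutathione, fell by 2.92 ± 0.24 (adjusted p = 3.49e-06), and Asns, asparagine synthetase, by 1.23 ± 0.10 (adjusted p = 4.46e-06), whereas Sesn3, a sestrin gene, rose by 0.77 ± 0.08 (adjusted p = 2.31e-05). Of 28 genes of DNA replication and S phase, 18 fell, 0 rose and 10 did not pass (median -0.31, camera adjusted p = 1.29e-08; adjusted p = 0.0919 with an estimated correlation), and 23 fell adjusted over the list alone. Uhrf1, Rrm2, Ung and Cdc45, which act in DNA methylation, nucleotide supply, base repair and replication, fell by 0.48, 0.47, 0.53 and 0.53. Under epithelial scaling 4 S phase genes were higher and 0 lower (median 0.13), and 6 stress-response genes were higher and 5 lower.

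Markers of ducts and of basal progenitors did not follow the end bud genes. Of 17 basal progenitor genes, 7 rose, 2 fell and 8 did not pass (median 0.41, camera adjusted p = 0.00384; adjusted p = 0.228 with an estimated correlation), and 8 rose adjusted over the list alone. That median was 0.18 without DMSO 1 and 0.25 without FGFRi 2. Dst, a linker of hemidesmosomes, rose by 0.82 ± 0.12, Snai2 by 0.98 ± 0.16, the laminin gene Lamb3 by 0.66 ± 0.13, and Ngfr by 0.79 ± 0.16 (SE, n = 3 each). Trp63, the basal-cell transcription factor, rose by 0.41 ± 0.12, a call lost without DMSO 1, DMSO 2, FGFRi 1 or FGFRi 2 (adjusted p up to 0.0769). The basal keratins Krt5, Krt14 and Krt15 differed by 0.48 ± 0.58, 0.47 ± 0.34 and 0.13 ± 0.37 (adjusted p = 0.623, 0.360 and 0.858). These sizes depended on single libraries: without DMSO 1 they were 0.033, 0.18 and -0.010. In the ductal list of 23, 6 rose, 5 fell and 12 did not pass, so that its median was -0.04, its mean 0.10 and its test downward and not called (camera adjusted p = 0.382). Its falling members included the potassium channel gene Kcnn4, by 1.73 ± 0.14, the keratins Krt8 and Krt18, by 0.64 and 0.51, and the transcription factor gene Elf5, by 0.44, while Krt19 rose by 0.65 ± 0.19, a call lost without DMSO 1 or FGFRi 1 (adjusted p up to 0.124). Adjusted over the list alone, 8 ductal genes rose and 7 fell, and under epithelial scaling 13 were higher and 1 lower.

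Genes of the mesenchyme around the epithelium rose, 14 of 17 with 0 lower (median 0.85, camera adjusted p = 1.47e-17; adjusted p = 0.0850 with an estimated correlation), and 15 adjusted over the list alone. Col1a1 and Col1a2, which encode collagen I, Pdgfra and Col5a2 were higher by 1.14 ± 0.12, 0.93 ± 0.10, 1.17 ± 0.12 and 0.83 ± 0.10 (SE, n = 3 each). Of 11 genes of epithelial-mesenchymal transition and migration, 9 rose and 0 fell (median 1.34, camera adjusted p = 1.23e-16; adjusted p = 0.0366 with an estimated correlation), among them Zeb2, by 1.56 ± 0.12, Zeb1, Prrx1 and the cadherin gene Cdh11, with 9 also adjusted over the list alone. Many of these genes are expressed by mesenchyme itself, whose list summed to 4651 ± 795 CPM in FGFRi and 2514 ± 30.5 in DMSO (SD, n = 3 each). In the Wnt signalling list, 15 of 26 rose, 1 fell and 10 did not pass (median 0.75, camera adjusted p = 1.29e-08; adjusted p = 0.0919 with an estimated correlation), and 18 rose adjusted over the list alone. Sfrp2, a secreted Wnt modulator, rose by 1.82 ± 0.13, the Wnt target Axin2 by 1.62 ± 0.18 and the receptor gene Lgr6 by 1.34 ± 0.18, while Sfrp1 fell by 0.58 ± 0.11.

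Skeletal muscle genes gave the largest rises, 15 of 16 with 0 lower (median 2.997, camera adjusted p = 1.82e-16; adjusted p = 0.108 with an estimated correlation), and 16 adjusted over the list alone. The contractile genes Myh8, Acta1, Actc1 and Myh3 were 18.4, 13.6, 11.5 and 8.27 times as high, and Alpk3, Mybpc1, Smyd1, Casq2, Myl1 and Mylk4, which act in the sarcomere or its calcium store, were 14.4 to 17.4 times as high. On the log2 scale, Casq2 moved from 3.99 to 5.26 without DMSO 2, Mybpc1 to 4.69 without DMSO 3 and Myh8 to 3.60 without FGFRi 3. The list summed to 205 to 900 CPM in the FGFRi libraries and 34.5 to 106 CPM in DMSO. Schwann cell and glial genes rose in 6 of 11 (median 1.30, camera adjusted p = 4.99e-04; adjusted p = 0.145 with an estimated correlation), and in 8 adjusted over the list alone, with S100b, Ednrb and Cdh19 higher by 1.29 ± 0.21, 1.44 ± 0.27 and 1.64 ± 0.35 (SE, n = 3 each). S100a8 and S100a9, which are abundant in neutrophils, had 0 counts in all 3 FGFRi libraries and 6.58 ± 8.27 and 6.76 ± 5.93 CPM in DMSO, so that they were at least 71.9-fold and 73.8-fold lower against a floor of 3 counts over the group. These levels were highest in DMSO 3, without which the bounds were 19.9-fold and 38.1-fold, and the S100a8 call was lost without FGFRi 3 (adjusted p = 0.05004). Ddx3y, a Y-linked gene, was read at 50.6 CPM in DMSO 2 and 0 in each FGFRi library.

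Of 28 genes of mitosis 13 fell and 0 rose (median -0.27, camera adjusted p = 3.78e-07; adjusted p = 0.232 with an estimated correlation). Of 19 genes of cholesterol synthesis 10 fell and 0 rose (median -0.30, camera adjusted p = 2.24e-07; adjusted p = 0.124 with an estimated correlation). Under epithelial scaling these medians turned to 0.17 and 0.13, with 5 mitosis genes higher and 0 lower, and 6 cholesterol genes higher and 1 lower. By camera, 23 of 36 lists were called with the inhibitor, 11 upward and 12 downward, 3 with an estimated correlation and 26 by fry. Leaving out FGFRi 1 lowered the gene count to 1896 and leaving out DMSO 2 to 2161, and 69 of 82 named genes called kept their call in all 6 such fits. Scaling to epithelial genes moved the median of all genes by 0.44 on the log2 scale, so that 8239 genes were higher and 171 lower, and scaling by library totals left 1303 calls, 1018 of them higher. Direction of a gene is thus stated relative to all tested RNA.

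**Figure D1:**
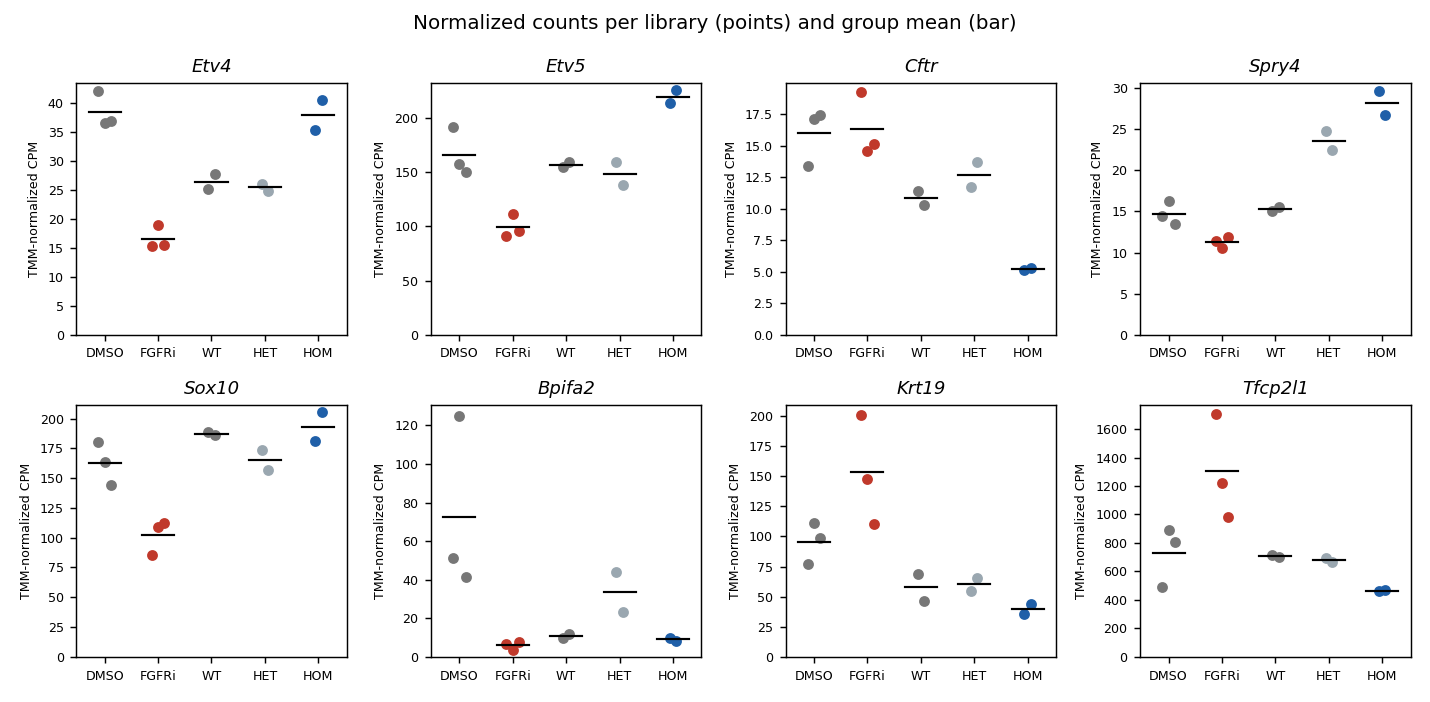
TMM-normalized CPM (vertical axis) of 8 genes in each library (points) of the 5 groups, with group means as bars. Etv4 lies lowest in the 3 FGFRi libraries, at 15.4 to 18.9 CPM, and at 35.4 and 40.6 CPM in the HOM libraries, above the 24.8 to 27.8 CPM of WT and HET. The mean of the DMSO libraries, also wild-type, lies near the HOM level.

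The HOM glands were compared with WT and HET littermates to ask what loss of the epithelial receptor isoform does. Of 23 duct markers 11 fell (adjusted p = 0.00168 with an estimated correlation): Ltf, lactoferrin, was read at 3.103 ± 0.995 CPM in HOM (SD, n = 2) and 14.3 ± 5.08 in the 4 controls, a log2 change of -2.09 ± 0.25 (SE). Of 27 tight-junction, 13 desmosome and 25 stratified-epithelium genes 12, 6 and 6 fell (adjusted p = 0.0397, 0.0795 and 0.237 with an estimated correlation). Of 17 mesenchymal and 16 skeletal muscle genes 8 and 9 rose (adjusted p = 0.140 for each in that test). The FGF/ERK response list was not called, and Etv4 and Etv5 rose. Of 15859 genes, 546 were higher and 387 lower, 145 and 61 of them by at least 2-fold. Both HOM libraries were female and all 4 controls male, so no value in this comparison separates genotype from sex, and with sex as a covariate, estimated from the DMSO libraries alone, 46 genes were called.

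Ductal genes fell in 11 of 23, with 0 higher and 12 that did not pass (median -0.61, camera adjusted p = 1.22e-18; adjusted p = 0.00168 with an estimated correlation), and in 17 adjusted over the list alone. Ltf led (adjusted p = 3.03e-04), with the chloride channel gene Cftr, by -1.17 ± 0.16 (adjusted p = 6.20e-04), the epithelial ETS factor Ehf, by -0.61 ± 0.08 (adjusted p = 6.46e-04), and Krt8, by -0.72 ± 0.11 (adjusted p = 0.00119). These 4 genes kept their call without any 1 library, as did the tight-junction genes Ocln, Cldn4 and Cgn. Of 27 tight-junction genes, 12 fell, 0 rose and 15 did not pass (median -0.33, camera adjusted p = 6.23e-14; adjusted p = 0.0397 with an estimated correlation), and 17 fell adjusted over the list alone. Ocln fell by 0.66 ± 0.09, Cldn1 by 0.79 ± 0.13, Cldn4 by 0.54 ± 0.09 and Cgn by 0.52 ± 0.09, and Cldn1 lost its call without HOM 2 (adjusted p = 0.0879). Under epithelial scaling 6 ductal genes were lower and 0 higher, and 2 tight-junction genes lower and 3 higher.

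Desmosome genes fell in 6 of 13 with 0 higher (median -0.68, camera adjusted p = 6.33e-10; adjusted p = 0.0795 with an estimated correlation), and in 10 adjusted over the list alone. Pkp2, Dsg2, Perp and Dsp, all parts of the desmosome, fell by 0.68 ± 0.10, 0.44 ± 0.08, 0.45 ± 0.09 and 0.55 ± 0.12. Genes of stratified differentiation fell in 6 of 25 with 0 higher (median -0.90, camera adjusted p = 2.84e-09; adjusted p = 0.237 with an estimated correlation), and in 13 adjusted over the list alone. That median was -2.17 without HOM 2, or -1.09 with the 3 members at 0 in HOM 1 at their floor, and -0.45 without WT 1, or -0.50 with the 4 members at 0 in WT 2 at theirs. The envelope genes Ppl and Evpl were lower by -0.62 ± 0.11 and -0.82 ± 0.16 and the transcription factor genes Grhl1 and Zfp750 by -0.51 ± 0.10 and -0.43 ± 0.09. That list summed to 1057 CPM in WT 1 and 1107 CPM in DMSO 3, above the 301 to 777 CPM of the other 10 libraries. Evpl lost its call without HOM 1 (adjusted p = 0.0976) and Pkp2, Dsg2, Perp and Ppl without HOM 2 (up to 0.187), and Dsp, Grhl1 and Zfp750 without either (up to 0.160); Zfp750 also without WT 2. The protease inhibitor gene A2ml1, the adenylyl cyclase gene Adcy2 and Smgc, a submandibular secreted protein, fell by 3.33 ± 0.50, 2.09 ± 0.27 and 2.09 ± 0.47, of which Smgc lost its call without HOM 1 or HOM 2 (up to 0.231) and A2ml1 without HOM 2 (0.0734).

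Of 22 end bud and acinar genes, 6 fell, 0 rose and 16 did not pass (median -0.42, camera adjusted p = 5.44e-07; adjusted p = 0.223 with an estimated correlation), and 11 fell adjusted over the list alone. The mucin gene Muc19, Smgc and Bhlha15, a transcription factor of secretory cells, fell by 1.43 ± 0.30, 2.09 ± 0.47 and 0.80 ± 0.19, and Sox9 by 0.36 ± 0.09. Muc19 lost its call without HOM 1 or HOM 2 (adjusted p up to 0.167), and Bhlha15 and Sox9 without any 1 of 5 libraries, both HOM, both WT or HET 1 (up to 0.235). Kit, Sox10 and Aqp5 differed from controls by 0.022 ± 0.10, 0.14 ± 0.10 and -0.41 ± 0.19 (adjusted p = 0.941, 0.535 and 0.252). Under epithelial scaling 4 end bud genes were lower and 3 higher. Of 15 pan-epithelial genes 6 fell, 0 rose and 9 did not pass (median -0.32, camera adjusted p = 4.32e-09; adjusted p = 0.140 with an estimated correlation), and 13 fell adjusted over the list alone. Esrp1, Spint1, Llgl2 and Spint2 fell by 0.32, 0.42, 0.40 and 0.41, and Cdh1 by 0.47 ± 0.10, calls that each ended without HOM 1 or HOM 2 (adjusted p up to 0.281), for Esrp1 and Cdh1 also without WT 2, for Spint1 and Llgl2 without WT 1, and for Spint2 without any 1 of the 6. Epcam and Cdh3 differed by -0.27 ± 0.09 and 0.14 ± 0.10 (adjusted p = 0.0961 and 0.523). The list summed to 1242 ± 61.8 CPM in HOM, 1633 ± 38.0 in WT and 1462 ± 83.2 in HET (SD, n = 2 each).

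In the FGF/ERK response list of 23, 3 rose, 1 fell and 19 did not pass (median 0.02, camera adjusted p = 0.382), and 4 rose and 2 fell adjusted over the list alone. Etv4 was read at 38.0 ± 3.73 CPM in HOM (SD, n = 2) and 26.0 ± 1.32 in the 4 controls and rose by 0.56 ± 0.10 (adjusted p = 0.00493). The wild-type DMSO glands of the other arm had a mean Etv4 level near that of HOM. Etv5 rose by 0.52 ± 0.10 (adjusted p = 0.00657) and Spry4 by 0.56 ± 0.10 (adjusted p = 0.00342), while Etv1 fell by 0.80 ± 0.15 (adjusted p = 0.00657). Without HOM 2 the calls of Etv4, Etv5 and Etv1 were lost (adjusted p = 0.147, 0.132 and 0.171), and that of Spry4 was kept. Spry1, Spry2 and Dusp6 differed by 0.025 ± 0.08, 0.21 ± 0.09 and -0.017 ± 0.11 (adjusted p = 0.920, 0.224 and 0.961), and Dusp6 turned to 0.30 under epithelial scaling. That scaling moved the median of all genes in HOM by 0.31, so the changes of this whole list lie higher under it. Among basal genes, Krt15 fell by 1.60 ± 0.43 (adjusted p = 0.0404), a call lost without HOM 1, HOM 2, HET 1, HET 2 or WT 1 (up to 0.239), where the change was -0.88 without WT 1. Krt5, Krt14, Krt19 and Trp63 differed by -1.66 ± 0.70, -0.65 ± 0.36, -0.57 ± 0.21 and -0.030 ± 0.12 (adjusted p = 0.198, 0.360, 0.136 and 0.935). Without WT 1, Krt5 and Krt14 differed by -0.76 and -0.30.

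Mesenchymal genes rose in 8 of 17 with 0 lower (median 0.45, camera adjusted p = 3.88e-10; adjusted p = 0.140 with an estimated correlation), and in 13 adjusted over the list alone. Pdgfrb, the PDGF receptor of pericytes and fibroblasts, rose by 0.87 ± 0.10 (SE, adjusted p = 2.32e-04), Fap by 0.71 ± 0.14, Col5a1 by 0.45 ± 0.09 and Col5a2 by 0.51 ± 0.10. Genes of epithelial-mesenchymal transition and migration rose in 8 of 11 with 0 lower (median 0.62, camera adjusted p = 8.43e-11; adjusted p = 0.0795 with an estimated correlation), and in 9 adjusted over the list alone, among them Zeb2, by 0.87 ± 0.11, Zeb1, by 0.79 ± 0.12, Snai1, by 0.94 ± 0.19, and Cdh11, by 0.58 ± 0.13. Basement membrane and matrix adhesion genes rose in 10 of 32 with 0 lower (median 0.19, camera adjusted p = 2.88e-04; adjusted p = 0.306 with an estimated correlation), and in 12, with 3 lower, adjusted over the list alone. Without HET 1 that median was 0.11. The integrin gene Itga9, nidogen Nid1, collagen Col18a1 and laminin Lama2 rose by 0.63 ± 0.09, 0.66 ± 0.09, 0.76 ± 0.12 and 0.62 ± 0.11. Pdgfrb, Zeb1, Zeb2, Itga9 and Nid1 kept their call without any 1 library. Col5a1, Col18a1 and Lama2 lost it without HOM 2, Fap without HOM 1, Col5a2 and Snai1 without either, and Cdh11 also without HET 2 or WT 2 (adjusted p up to 0.235).

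Skeletal muscle genes rose in 9 of 16 with 0 lower (median 2.27, camera adjusted p = 3.59e-16; adjusted p = 0.140 with an estimated correlation), and in 15 adjusted over the list alone. The muscle regulators Myod1 and Myog were 10.4 and 7.58 times as high, and the muscle genes Actc1, Chrna1, Des and Tnnt1 8.10, 8.11, 6.09 and 4.76 times. These sizes rested on WT 1, as Myod1, Myog, Actc1 and Chrna1 had 0 counts in WT 2. Without WT 1 they were at least 5.68-fold, 6.88-fold, 13.9-fold and 4.37-fold higher against a floor of 3 counts in WT 2. The log2 changes of Des and Tnnt1 moved from 2.61 and 2.25 to 3.1997 and 3.03. With members at 0 at their floor, the list median was 2.25 over all libraries and 2.03 without WT 1, where 8 members were at 0. The list summed to 252 ± 14.8 CPM in HOM, 184 ± 75.4 in HET and 21.1 ± 3.66 in WT (SD, n = 2 each). All 6 calls were lost without HOM 2 (adjusted p up to 0.164), those of Myog and Tnnt1 also without WT 2, and that of Tnnt1 without HOM 1. Schwann cell and glial genes rose in 4 of 11 with 0 lower (median 0.71, camera adjusted p = 6.03e-07; adjusted p = 0.0795 with an estimated correlation), and in 6 adjusted over the list alone. Ednrb rose by 1.44 ± 0.24, Cdh19 by 1.69 ± 0.30, Foxd3, a neural crest factor, by 1.71 ± 0.38 and Gfra3 by 1.64 ± 0.43. Foxd3 turned to -0.73 with sex as a covariate. Cdh19 lost its call without HOM 2 (0.0592), Foxd3 without HOM 1, HOM 2 or WT 2 (up to 0.178), and Gfra3 without any 1 library but WT 1 (up to 0.428), where it rose by 2.25.

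Among the largest changes were genes of sex and of sequence copies. Xist was read at 954 ± 154 CPM in HOM (SD, n = 2) and 1.93 ± 1.64 in the 4 controls, while the Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty were read at 44.9, 27.9, 32.2 and 22.7 CPM in controls and at 0.0400, 0, 0.0207 and 0.0207 in HOM. Eno1b, a retrogene of enolase, was read at 23.5 ± 0.557 CPM in HOM and 0.139 ± 0.103 in controls, and Hist1h3f, a histone gene with near-identical paralogs, at 105 ± 3.47 CPM in HOM, 57.3 ± 2.55 in WT and 0.700 ± 0.0804 in HET. All 4 Y-linked calls ended without HOM 2 (adjusted p up to 0.235), and all but that of Kdm5d without HOM 1. Reads shared among copies leave the source of such counts uncertain. By camera 23 of 36 lists were called in HOM, 12 upward and 11 downward, 2 with an estimated correlation and 13 by fry. Leaving out HOM 2 lowered the gene count to 140, HOM 1 to 501, WT 1 to 574 and WT 2 to 516, and 18 of 67 named genes called kept their call in all 6 such fits. Scaling to epithelial genes moved the median of all genes by 0.31, with 4907 genes then higher and 109 lower, and library totals moved it by 0.15, with 536 higher and 96 lower.

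Each control genotype was set against HOM in turn. Ductal genes were lower against both: 11 of 23 fell against WT (median -0.54, camera adjusted p = 1.25e-14; adjusted p = 0.00406 with an estimated correlation) and 6 against HET (median -0.61, camera adjusted p = 1.91e-19; adjusted p = 0.00133 with an estimated correlation). Ltf, Cftr, Ehf, Krt8, Ocln, Cldn4 and Cgn fell against each, as Etv4 and Etv5 rose against each. Mesenchymal genes rose in 12 of 17 against WT (camera adjusted p = 2.46e-15; adjusted p = 0.108 with an estimated correlation) and in 0 against HET, where the median was 0.15 (camera adjusted p = 0.00702; adjusted p = 0.517 with an estimated correlation). Muscle genes rose in 14 of 16 against WT (camera adjusted p = 1.70e-22; adjusted p = 0.108 with an estimated correlation), and against HET the list was not called (adjusted p = 0.0764). HOM differed from WT at 1199 genes, 713 higher and 486 lower, and from HET at 237, 98 higher and 139 lower. Leaving out HOM 2, WT 1 or WT 2 lowered the count against WT to 299, 372 and 338, and leaving out HOM 2, HOM 1, HET 2 or HET 1 lowered that against HET to 33, 58, 61 and 93. Epithelial scaling moved the medians of all genes by 0.39 against WT and 0.23 against HET, with 5582 genes then higher and 88 lower against WT and 663 higher and 68 lower against HET, and library totals moved that against WT by 0.22.

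HET glands were compared with WT as well. Mesenchymal genes rose in 7 of 17 (median 0.57, camera adjusted p = 9.40e-13; adjusted p = 0.336 with an estimated correlation), muscle genes in 6 of 16 (camera adjusted p = 1.45e-28; adjusted p = 0.336 with an estimated correlation) and ductal genes in 0. Summed mesenchymal counts were 4029 ± 260 CPM in HET, 2695 ± 95.2 in WT and 4327 ± 151 in HOM (SD, n = 2 each). Aldh1a2, an enzyme of retinoic acid synthesis, was 2.197 times as high in HET, Spon2, a matrix protein, 2.40 times and Myof, a membrane repair protein, 2.93 times. The smallest p-values in the other direction fell to the processed pseudogenes Gm13394, Gm8399 and Gm8210 and to Gm4737, which is annotated as protein-coding. Each was at 0.154 to 0.435 CPM in HET and 11.1 to 39.2 CPM in WT. Hist4h4 was also among them, at 0.351 times its WT level. Eif3j2 and Gm15772 were at 10.5 and 68.0 CPM in HET and 0.328 and 0.943 in WT. In all, 135 genes were higher and 59 lower, counts that fell in sum to 25 without WT 1, 31 without WT 2 and 49 without HET 2. Epithelial scaling moved the median of all genes by 0.16 and library totals by 0.14.

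The effect of the inhibitor was then tested against that of the deletion. FGF/ERK response genes were lower with the inhibitor than in HOM: 8 of 23 passed downward and 0 upward (median difference -0.49, camera adjusted p = 1.66e-15; adjusted p = 0.0210 with an estimated correlation), and 14 adjusted over the list alone. Etv4 differed by -1.76 ± 0.15 on the log2 scale (SE, adjusted p = 1.30e-05), Etv5 by -1.26 ± 0.14, Epha2 by -1.05 ± 0.15 and Spry4 by -0.96 ± 0.15. Ductal genes differed the other way, 6 of 23 higher and 1 lower (median 0.70, camera adjusted p = 1.80e-09; adjusted p = 0.0112 with an estimated correlation), with 14 and 1 adjusted over the list alone. Among them were Ltf, by 1.81 ± 0.31, Tfcp2l1, a duct transcription factor, by 1.42 ± 0.29, and Cftr, by 1.16 ± 0.21, whereas Kcnn4 differed by -1.44 ± 0.20. Of 26 Wnt genes, 5 differed upward and 1 downward (median 0.74, camera adjusted p = 1.71e-09; adjusted p = 0.126 with an estimated correlation), with 10 and 1 adjusted over the list alone, among them Sfrp2, by 1.94 ± 0.18, Lgr6, by 1.75 ± 0.27, Axin2, by 1.46 ± 0.25, and Wnt5b, by 0.82 ± 0.15. The Wnt median was 0.48 without WT 1, or 0.75 with Lef1 and Notum, at 0 in WT 2, at their floor.

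Stress-response genes were lower with the inhibitor than in HOM in 5 of 18 and higher in 1 (median -0.35, camera adjusted p = 3.76e-06; adjusted p = 0.180 with an estimated correlation), with 9 and 1 adjusted over the list alone. Chac1 and Trib3 differed by -2.83 ± 0.33 and -2.23 ± 0.29, Asns by -0.81 ± 0.15 and Phgdh, which starts serine synthesis, by -0.57 ± 0.12. End bud genes differed downward in 5 of 22 and upward in 0 (median -0.75, camera adjusted p = 3.84e-06; adjusted p = 0.281 with an estimated correlation), with 10 and 1 adjusted over the list alone, among them Kit, Sox10, Bpifa2 and Dcpp1, by -1.08 ± 0.14, -0.79 ± 0.15, -2.53 ± 0.57 and -1.43 ± 0.31. Bpifa2 differed by -1.84 without DMSO 2 and Dcpp1 by -2.15 without FGFRi 3. Basal genes differed upward in 2 of 17, Lamb3, by 1.63 ± 0.19, and Pdpn, by 0.84 ± 0.17 (median 0.60, camera adjusted p = 2.87e-06; adjusted p = 0.170 with an estimated correlation), with 12 higher and 3 lower adjusted over the list alone. Tight-junction and pan-epithelial lists were not called (adjusted p = 0.2498 and 0.268). In all, 216 genes differed upward and 223 downward, and 19 of 36 lists were called, 10 upward and 9 downward, 2 with an estimated correlation and 10 by fry. The gene count fell to 77 without HOM 2, 226 without HOM 1, 216 without WT 1, 240 without WT 2, 267 without HET 2, 251 without DMSO 1, 235 without FGFRi 1 and 277 without FGFRi 2. Without HOM 2 the calls of Asns, Axin2, Bpifa2, Cftr, Dcpp1, Pdpn, Phgdh, Sox10 and Tfcp2l1 ended (adjusted p 0.0545 to 0.159); Bpifa2, Dcpp1, Pdpn, Phgdh and Tfcp2l1 also lost theirs without at least 1 other library. With sex as a covariate 451 genes differed, 314 upward and 137 downward. Epithelial scaling moved the median of all genes by 0.13, with 187 upward and 96 downward, and library totals by -0.13.

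Genes changed by both the inhibitor and the deletion were counted, the compared libraries having none in common. In both, 358 genes were higher, where 53.1 were expected for independent calls, and 180 lower, where 41.5 were expected (Fisher's exact p = 4.49e-236 and 1.64e-73, genes not being independent). In opposite directions 8 and 24 genes were called, where 37.7 and 58.6 were expected. Independence is not the right expectation, as in both comparisons male libraries lay among the controls alone. Without DMSO 2, the only male library of the inhibitor arm, 352 genes were still higher and 135 lower in both. The inhibitor comparison then held female libraries alone, which argues against this shared imbalance as the source of most shared calls. With library totals 317 genes were higher and 20 lower in both, and under epithelial scaling 3676 and 20. With HET alone as the control of HOM, 38 were higher and 66 lower in both. Of the 933 genes called in HOM, 775 (83.1%) had the same sign with the inhibitor, against 63.5% of all genes. Muscle genes led the shared rises: Unc45b, Mymk, Myl1, Lmod3 and Actc1 were among them, with Arpp21. In HOM against HET the muscle list was not called. Shared falls were led by the 4 Y-linked genes and Gm29650, which was read at 0 in both FGFRi and HOM libraries and at 1.70 CPM in controls, and by A2ml1. With the inhibitor, Eif2s3y, Uty, Kdm5d and A2ml1 lost their call without DMSO 2 (adjusted p up to 0.919), A2ml1 also without FGFRi 1 or FGFRi 2, Kdm5d without FGFRi 3, and Gm29650 without any 1 of 4 libraries. Shared calls fell to 82 without HOM 2, 257 without HOM 1, 337 without WT 1 and 320 without WT 2, and with sex as a covariate 9 were left. Of these muscle genes Actc1 lost its HOM call without HOM 2 alone, and each of the others without at least 4 of the 6 libraries (adjusted p up to 0.246).

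**Figure D2:**
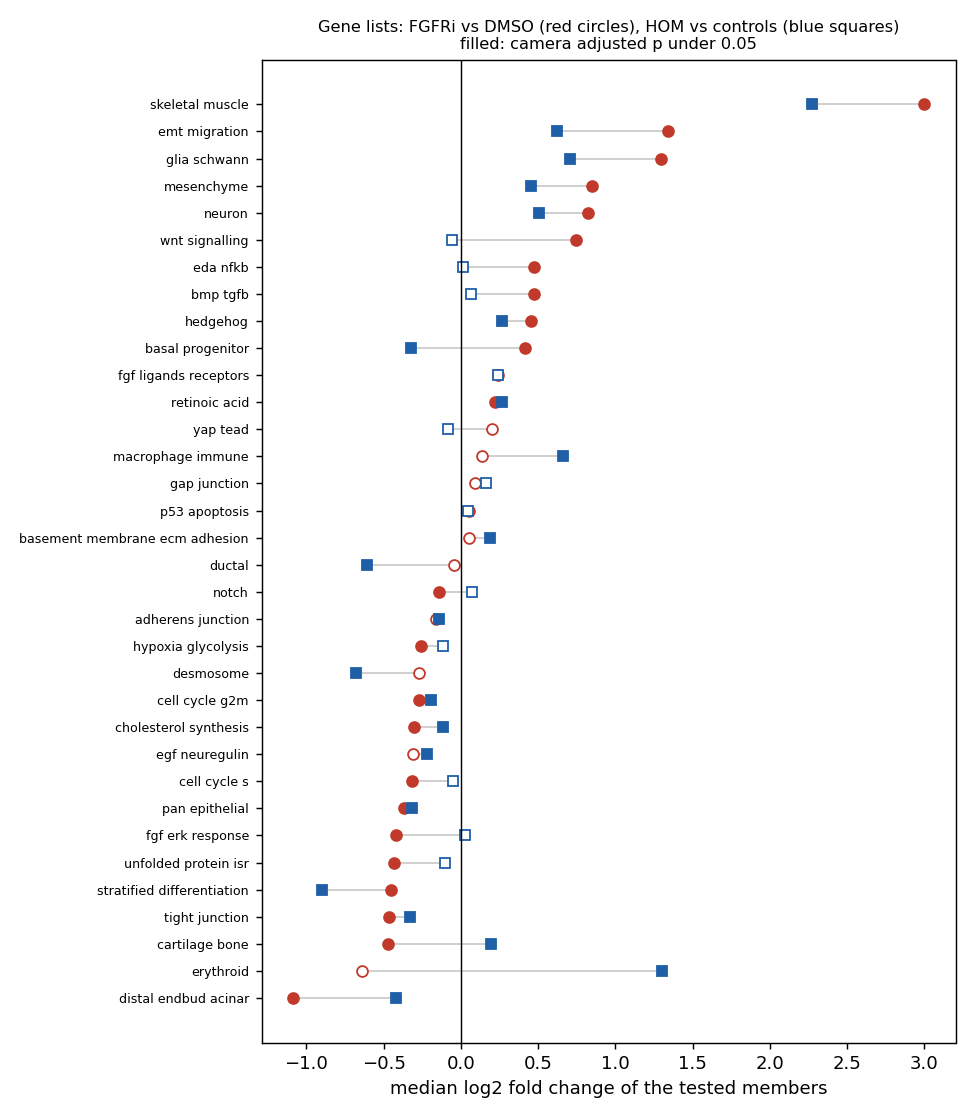
Median log2 fold change of the tested members (horizontal axis) of 34 gene lists (vertical axis) with the inhibitor (red circles) and in HOM (blue squares); filled symbols are lists called by camera at a preset correlation. The FGF/ERK response list lies at -0.42 and 0.02 and the ductal list at -0.04 and -0.61, and scaling to epithelial genes would shift the circles right by 0.44 and the squares by 0.31. Left out are 2 lists with a member at 0 in every library on 1 side of a comparison; the muscle list, with Mymk at 0 in WT but not in HET, is shown at its fitted HOM median of 2.27 (2.25 with Mymk at its floor).

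DMSO and WT glands, the controls of each arm, were compared as a measure of background between the arms, where solvent, colony, dissection and sex cannot be told apart, as 2 of 3 DMSO libraries were female and both WT libraries male. Of 15859 genes, 202 were higher and 156 lower in DMSO. That balance turned to 188 and 292 with sex as a covariate and to 130 and 154 under epithelial scaling. With library totals it was 249 and 74. The smallest p-values fell to gene copies: Hist1h2al, Vcp-rs, Tpm3-rs7, Eno1b and Gm4735 were at 194, 84.3, 61.1, 62.1 and 23.8 CPM in DMSO and at 0.0732 to 1.93 CPM in WT. Rps13-ps1, Dcpp3, Gm8399 and Gm25939 were at 0.0173 to 0.391 CPM in DMSO and 39.2 to 84.2 in WT, and Rpl29 at 22.6 and 148 CPM. Symbols of clone, pseudogene or related-sequence type made up 20.1% of these calls, 1.26% of those with the inhibitor and 9.89% of tested genes. Etv4, Kit, Chac1 and Trib3 were higher in DMSO than in WT, by 0.54 ± 0.11, 0.53 ± 0.11, 1.61 ± 0.24 and 1.73 ± 0.22 (SE), so the controls of the arms differed in genes that the inhibitor lowered. For Etv4 this background difference was about as large as its rise of 0.56 in HOM. Ductal genes were higher in 3 of 23 (camera adjusted p = 0.00102; adjusted p = 0.255 with an estimated correlation). Without WT 1 and without WT 2, 110 and 116 genes were called, and library totals moved the median of all genes by 0.15.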

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

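Of the tests weighed in this part, all were chosen after the results they bear on had been seen, while the test of the difference between both effects was fixed before the data were examined. That test set the effect of the inhibitor against the effect of the deletion and called 439 genes and 19 lists. What singles out each value here is that difference, on the log2 scale, positive where the effect of the inhibitor was the higher. Both HOM libraries were female and their controls male, and the arms came from different control glands, so sex and background are part of each difference.

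List medians differed by -0.49 for FGF/ERK response genes, -0.75 for end bud and acinar genes, and -0.35 for stress-response genes. They differed by 0.70 for ductal, 0.60 for basal progenitor and 0.74 for Wnt genes. Among FGF/ERK response genes, Etv4 differed by -1.76, Etv5 by -1.26, Epha2 by -1.05, Spry4 by -0.96 and Spry2 by -0.52. Among duct genes Ltf differed by 1.81, Cftr by 1.16, Tfcp2l1 by 1.42, Krt19 by 1.22 and Kcnn4 by -1.44. Among Wnt genes Sfrp2 differed by 1.94, Lgr6 by 1.75, Axin2 by 1.46 and Wnt5b by 0.82. Stress-response genes gave -2.83 for Chac1, -2.23 for Trib3, -0.81 for Asns and -0.57 for Phgdh. End bud genes gave -1.08 for Kit, -0.79 for Sox10, -1.43 for Dcpp1, -2.53 for Bpifa2 and -1.07 for Aqp5, and the basal genes Lamb3 and Pdpn gave 1.63 and 0.84. Outside these lists, Cyp1b1, Fat4, Prss12 and Aldh3a1 differed by 2.70, 1.45, 2.63 and 1.59. In the other direction Eno1b, Sema3b, Crispld2, Stc2 and Aldh1l2 differed by -8.24, -1.82, -3.38, -1.70 and -1.81.

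Of 34 named genes called here, 22 kept their call in all 12 fits that left out 1 library. Without HOM 2 the calls of Aqp5, Spry2, Krt19, Bpifa2, Dcpp1, Pdpn, Phgdh, Tfcp2l1, Asns, Axin2, Cftr and Sox10 ended. Those of Aqp5 and Spry2 ended in 10 fits each (adjusted p up to 0.230 and 0.208), and that of Krt19 in 7 (up to 0.133). The count of 439 fell to 77 without HOM 2.

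FGF/ERK response genes fell with the inhibitor, while in HOM the list was not called and Etv4 and Etv5 were higher. After scaling to pan-epithelial genes, 8 of the 14 lower genes were still lower, which argues against a smaller epithelial share as the whole cause for Epha2, Ccnd1, Dusp4, Etv4, Etv1, Shisa2, Etv5 and Egr1. The other 6, Spred1, Spry1, Spry2, Spry4, Dusp6 and Dusp5, had a median of 0.040 after that scaling, 5 of them at 0.023 to 0.12 and Dusp5 still at -0.39 (adjusted p = 0.121), and there the share and a fall in signalling cannot be told apart, because these genes were picked by their lost call and the scaling assumes that epithelial genes are not themselves regulated. In the test of the difference 8 of the list passed, Epha2, Ccnd1, Etv4, Shisa2, Spry2, Etv5, Egr1 and Spry4. For these genes except Spry2 it argues against too few HOM libraries as the reason. The Spry2 call (adjusted p = 0.0495) ended in 10 of the 12 fits that left out 1 library, so for Spry2 this reason stays open. Spred1, Spry1, Dusp4, Dusp6, Etv1 and Dusp5, also lower with the inhibitor, did not pass (adjusted p 0.0824 to 0.392). For them this reason stays open, and Etv1 itself changed by -0.80 in HOM (adjusted p = 0.00657). Incomplete deletion or a wrong label cannot be told apart from an effect of genotype, as Fgfr2 differed by -0.071 over the whole gene and the deleted exon is not counted apart. Sex and background stay open. So does the unlike reach of both arms, as the compound inhibits FGF receptor kinases and the cross deletes the Fgfr2b isoform in epithelium.

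With the inhibitor, lists of epithelial markers moved apart: end bud genes fell, while part of the ductal and basal genes rose and others fell. The basal keratins Krt5, Krt14 and Krt15 did not pass (adjusted p = 0.623, 0.360 and 0.858). Which cells expressed the basal genes that rose was not measured. A lower epithelial share alone would lower epithelial genes alike. After scaling to pan-epithelial genes, however, which left 171 of 15859 genes lower, 12 of 22 end bud genes were still lower. Ductal and basal genes were not used in this test, because that scaling moved the median of all genes upward by 0.44. Sex of the embryos as the whole cause is argued against by the comparison without the male DMSO library, in which 13 end bud genes fell and 13 mesenchymal genes rose. A change in cell fate and a change in the number of cells of each epithelial type may each give this pattern, and counts of whole glands do not decide between them.

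Retrogenes and paralogs such as Eno1b switched on or off between genotype groups. Of 21 genes off X and Y that differed by at least 3 on the log2 scale between HOM and HET, 6 (28.6%) also did so between DMSO and WT, against 0.496% of the 15334 genes tested off X and Y (Fisher's exact p = 6.20e-10, genes not independent), consistent with differences in genetic background between embryos. Loss of FGF signalling is argued against by a median change of 0.26 (range -0.50 to 0.72) with the inhibitor, in the direction of HOM, over the 12 pseudogenes that differed as much between HOM and controls. Low counts are argued against by a median of 137 counts per library on the higher side, with 10 of the 12 over 50. These tests on signalling and on counts were run over all 39 such genes off X and Y before being narrowed to pseudogenes, with bounds reworded after the values were seen, and over the 39 the median change was 0.63 and the median count 56.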

How the results depend on the processing

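Planned settings were fixed before the data were examined, and those on sex, on the pair of libraries high in stratified-epithelium genes and on crossed WT numbers were chosen after seeing the data. Camera compares a list with other genes, so a shift of all genes cannot turn it, and no described list turned by camera direction where called. Counts are genes unless lists are named, and the cause was not tested unless given.

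Scaling to pan-epithelial genes, which moved the median of all genes upward in each comparison but DMSO against WT, gave 8410 with FGFRi, 5016 in HOM, 5670 against WT, 731 against HET, 283 for the difference and 3696 shared. It reversed, with FGFRi, Cdh1 (0.073), Dusp6 (0.023), Esrp1 (0.077), Fgfr2 (0.13), Sox9 (0.23), Spry1 (0.068), Spry2 (0.12) and Spry4 (0.048), and in HOM Dusp6 (0.30). It turned the FGFRi medians of the FGF/ERK (0.023), pan-epithelial (0.077), S phase (0.13), stress-response (0.0099), ductal (0.41), mitosis (0.17) and cholesterol (0.13) lists. Library totals gave 1303 with FGFRi, 139 against HET, 169 for the difference and 337 shared.

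Without a filter, counts were 1449 in HOM, 667 against HET, 655 for HET against WT, 1003 for the difference and 797 for DMSO against WT. Models of the compared groups alone gave 1406 in HOM, 2036 against WT and 444 against HET. A minimum log2 change of 1, stricter by construction, gave 822 with FGFRi, 206, 379 and 90 in HOM against both controls, WT and HET, 88 for HET against WT, 183 for the difference, 175 for DMSO against WT and 82 shared. HET alone as control gave 237 in HOM and 104 shared. A block by replicate number gave 277 for the difference. Deviations of each library from its group mean, in log CPM, were compared across genes. Those of same-number FGFRi and DMSO libraries correlated at r = -0.117 to -0.025, and 0 of 3 DMSO libraries best with their own number.

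With sex as a covariate, which is confounded with HOM and estimated within DMSO alone, the uncalled ductal list with FGFRi had a median of 0.059 and FGF/ERK in HOM one of -0.029, both turned, and counts were 2153 with FGFRi, 46 in HOM, 116 against WT, 45 against HET and 9 shared, and 13 lists in HOM. It moved the fitted value of Gm29650, which is at 0 in FGFRi and HOM and whose fit gives neither a size nor a bound, to 0 with FGFRi and 0.10 in HOM, and moved Foxd3 in HOM to -0.73. Without DMSO 3 and WT 1, the pair high in stratified-epithelium genes, counts were 568 in HOM, 388 against WT, 40 for HET against WT, 257 for the difference, 99 for DMSO against WT and 332 shared.

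Lists called with an estimated correlation were 3 with FGFRi, 2 in HOM and 2 for the difference, and by fry 13 in HOM and 10 for the difference.

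Leaving out 1 library gave 1896 to 3099 with FGFRi, 140 to 658 in HOM, 299 to 858 against WT and 33 to 93 against HET. It gave 25 to 195 for HET against WT, 77 to 560 for the difference, 110 to 370 for DMSO against WT and 82 to 561 shared. Lists ran from 22 to 25 with FGFRi, 21 to 24 in HOM and 17 to 21 for the difference, and the fitted value of Gm29650 with FGFRi, no size or bound either, from -6.89 to 0, both groups being at 0 without DMSO 2. The median of the ductal list ran from -0.11 to 0.059 with FGFRi and that of FGF/ERK from -0.022 to 0.074 in HOM. In groups of 2, the lone library left is assumed to vary like the other groups.

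Of the values of single named genes, the direction held and the call was lost for 49 with library totals, 28 with epithelial scaling, 75 with the sex covariate, 79 with a minimum change of 1, 17 with DESeq2's Wald test, 23 with limma-voom and 8 with the block. Of described lists, 22 lost their call with an estimated correlation, 4 by fry and 3 with the sex covariate. The depth of these libraries limits genes of few counts, and simulated changes of 1.5-fold in the difference were recovered in 11.9%.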

Other observations

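Of the tests in this part, the one on a shared embryo was chosen after its result was seen, and those on the aryl hydrocarbon receptor and on other splits were written before. Cyp1b1, a target of that receptor, was 6.28 times as high with the inhibitor and was not called in HOM. Of 7 other genes of the receptor's battery, 4 were tested and 3 rose with the inhibitor. Cyp1a1, Cyp1a2 and Ugt1a6a were not among the genes tested. Nqo1, Aldh3a1 and Ahrr were higher by 1.19 ± 0.28, 1.03 ± 0.16 and 2.70 ± 0.45 on the log2 scale (SE, n = 3 each), and Tiparp differed by 0.052 ± 0.12 (adjusted p = 0.810). Their median of 1.11 met the bound set beforehand for a response of this receptor to the inhibitor compound. That median leaves out the members that did not pass the count filter, Cyp1a1 among them, for which no rise was seen. In HOM none of these 4 was called, with Ahrr at 1.18 ± 0.43 and Aldh3a1 at -0.56 ± 0.17 (SE, adjusted p = 0.134 and 0.0630). The difference from HOM passed for Aldh3a1 alone of these 4, and no measurement of the receptor itself was made.

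The 6 libraries of DMSO and FGFRi can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 3245 genes and the highest of the others 8, so that 1 split, the real one, gave as many. Each other split mixed DMSO and FGFRi libraries, so an effect of the inhibitor would widen the spread within its groups. Their low counts are thus no measure of what chance would give.

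In each genotype group, both libraries were of 1 sex, in 3 of 3 pairs. Of 63 genes off X and Y, with the skeletal muscle list left out but other muscle genes such as Des and Myl1 kept, that differed by at least 8-fold between any pair of the 6 libraries, 24 (38.1%) did so within a genotype pair. That share met the bound set for separate embryos, but the reading was changed to undecided after it was seen. The change was made because 12 of the 24 are stratified-epithelium or ribosomal-RNA-like genes, which may vary for other reasons, and this was not tested. The rest include Nkx2-3, at 0.151 CPM in HET 1 and 8.28 CPM in HET 2. Of 15 such genes with clone, pseudogene or related-sequence symbols, 1 differed within a pair. That was Gm15564, at 946 CPM in HET 1 and 90.1 CPM in HET 2, which was itself counted as ribosomal-RNA-like. None of the rest of these copies differed within a pair. Whether both libraries of a genotype came from a single embryo cannot be told apart from separate embryos of like background. If they did, these pairs would hold technical spread only. The p-values of HOM and HET, whose spread is estimated over all 12 libraries, would then take spread between embryos from DMSO and FGFRi alone.

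S100a8 was read at 2.55, 1.09 and 16.1 CPM in DMSO 1 to 3 and S100a9 at 5.25, 1.72 and 13.3 CPM, while both were at 0 in all FGFRi and HET libraries. Of the genes called with the inhibitor 4.10% lay on X or Y, of those called in HOM 3.97%, and of all tested genes 3.31%.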
